A study of Homo sapiens with 2 samples.

How the data were processed

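Single-cell RNA and surface proteins were measured together in T cells of patients with lung cancer by CITE-seq, in which antibodies carry DNA barcodes that are counted beside the RNA of each cell. Per the labels, specimens from lung, brain and pleural fluid had been digested, frozen and thawed. Live CD45+ CD3+ cells had then been sorted, marked with hashtag antibodies that tell pooled specimens apart, and stained with the TotalSeq-C cocktail. The 2 libraries were prepared with the 10x Genomics 5′ chemistry and form 1 group with replicates 1 and 2. The sort removes cells without CD3, and enzyme digestion and freezing can change some surface proteins and stress genes.

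The deposited matrices hold counts, which the authors left without normalization: whole-number UMI counts per feature and cell barcode. Per the labels, Cell Ranger 3.1.0 and Seurat 3.0.0 were used on GRCh38, and the features in the files carry human and mouse prefixes, so reads had been placed on a combined reference. Each file listed 33538 human genes, 31053 mouse genes, 137 antibodies and 4 hashtags. The files name antibodies by the supplier's number alone, and protein names were assigned from recall of the supplier's numbering, without its sheet. In a check against RNA, 24 of 74 antibodies correlated best of all 137 antibodies with the RNA of their own gene in both libraries. If ranks were random and independent between the libraries, 0.00394 antibodies would do so. The libraries were read as 1 pool, so their ranks are not independent and this chance value is likely too low. The other 50 of the 74 did not rank first in both, and 63 antibodies were not tested in both libraries. Among these, CD11c, CD14, CD32, CD33 and CD64 were tested in neither library, so their names were not checked. The CD39 antibody was among the 50: it ranked 18 with the RNA of ENTPD1 in library 1 (correlation 0.0931) and 2 in library 2 (0.165). So were HLA-DR (ranks 12 and 2), CD38 (9 and 5), CD25 (5 and 6), CD44 (3 and 3) and CD103 (1 and 5). Hashtags were not mapped to a specimen or a patient by the labels. The T cell receptor libraries that the design text names were not analysed here.

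Library 1 held 6169210 human UMIs and library 2 held 3142209. Cells with at least 200 genes and at most 15% mitochondrial UMIs were kept, 1285 of 1287 barcodes in library 1 and 784 of 800 in library 2. Hashtags were called with HTODemux of Seurat 5.3.0 (positive quantile 0.99), which left 1181 and 670 cells with 1 hashtag. The share of cells under each hashtag differed by at most 3.13 percentage points between the libraries, under the limit of 10 points set in advance. Each hashtag was therefore summed over both libraries. For 4 of 4 hashtags the summed profile over 4052 genes correlated best with the same number in the other library. The CD8 gate took cells positive for the CD8 antibody and negative for CD4, by a mixture of 2 Gaussian components on the centred log ratio in each library, and the CD4 gate took the reverse.

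The CD39 classes, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A mixture on the centred log ratio of CD39 was to set the classes if its components differed by at least 1. They differed by 0.389 and 0.777 in the CD8 gate and by 0.250 and 0.444 in the CD4 gate of libraries 1 and 2, so the prepared fallback was used: the top against the bottom tertile of the centred log ratio in each library. Most cells had 0 CD39 UMIs, so the tertiles also followed the antibody total of a cell. The median antibody total was 365.5 UMIs in the top and 558 in the bottom tertile of the CD8 gate. After these counts had been seen, classes by CD39 UMI (at least 1 against 0) were added, with cells matched on antibody total (within 0.25 on the natural log scale) as a further alternative.

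UMIs were summed per hashtag and class where both classes held at least 10 cells. The sums were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test with hashtag as block), with Benjamini-Hochberg adjustment at 0.05. P-values therefore drew on the spread of the class difference between hashtags, which edgeR moderates by the spread over all genes. The CD8 gate gave 8 sums from 4 hashtags and the CD4 gate gave 4 sums from 2. Small p-values in the CD4 gate rest mostly on this moderation, since 2 hashtags alone measure little spread. The totals ranged from 90444 to 636141 UMIs in the CD8 gate and from 225552 to 2280617 in the CD4 gate by CD39 UMI. DESeq2 1.42.0 was the other tool. Proteins were tested in the same way over antibody counts, and also, in a test added after the data had been seen, as mean centred log ratios with limma 3.58.1. Antibodies used in the gates (CD39, CD8 and CD4) left before the adjustment. This was decided after the results were seen, because CD39 defines the classes and its own p had lowered the adjusted p of other proteins. With these antibodies kept in the adjustment, CD49f in matched CD8-gate cells had adjusted p = 0.0311 in place of 0.0608 and CD38 in CD4-gate tertiles 0.0266 in place of 0.0521. ENTPD1, which encodes CD39, and 91 sex-linked genes were left out of the findings, and T cell receptor and immunoglobulin segments were counted but not named. The interaction of CD39 class with gate was tested on the hashtags that held both gates. A fold change against a class with a count of 0 was bounded by putting 3 counts in its place.

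The 19 gene lists were CD8 dysfunction and tumour reactivity, tissue residency, naive and central memory, circulating effector, cytotoxicity, proliferation, interferon response, MHC class II with CD74, receptor-induced early genes, dissociation stress, regulatory T cell, T follicular helper, MAIT and innate-like, NK, B and plasma, myeloid, epithelial, stromal and endothelial, and erythrocyte and platelet. The 5 protein lists covered activation and dysfunction, residency, naive and memory, circulating effector, and other lineages. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, and an estimated correlation) and fry of limma. Named genes were those past the threshold with the same sign in every hashtag and a mean log2 CPM over 4: the 12 with the highest and the 12 with the lowest log2 fold change in the CD8 gate, 10 and 10 in the CD4 gate, 5 and 5 for the interaction, and 8 and 8 proteins per gate without a level minimum. Members of the lists could be named as well.

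Cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1) and named from 17 marker sets where at least 3 markers of a set were enriched, except that 1 cluster with NK genes was given a wider name after its genes were seen. Shares of cells carry exact (Clopper-Pearson) 95% intervals, which cover counting error alone. A CD39 UMI is found more often in deeply counted cells. Expected shares were therefore also computed after thinning cells to 200 antibody UMIs or 2000 RNA UMIs. Cells with fewer UMIs than that were left out of the thinned shares. Differences of shares between gates were tested with an exact two-sided sign-flip permutation test over hashtags. The test was tested on simulated data: with 200 genes shifted, it recovered 59% of 2-fold and 98% of 4-fold changes in the CD8 gate by CD39 UMI, with 6 false calls among 163. For the CD4 gate by CD39 UMI these values were 33%, 91% and 6 of 130. For CD8 tertiles they were 74%, 100% and 12 of 186, for CD4 tertiles 20%, 79% and 2 of 101, and for 20 shifted proteins in CD8 tertiles 50%, 100% and 1 of 16. For the CD103 contrast they were 67%, 95% and 11 of 173. All simulated hashtags had the same mean profile and the same shifts, with noise at the fitted dispersion. Differences between the real hashtags and counts carried by single cells were not simulated. The values therefore do not show how many calls in the real data are false.

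Alternatives were DESeq2, no gene filter, no hashtag block, the library or the hashtag within a library as unit, leaving out each hashtag, no cell filter, removal of the top 2% of cells by UMIs, a lineage gate by RNA, classes by ENTPD1 UMI or by isotype controls, and other scalings of the antibody counts. After the data had been seen, further alternatives were added: at least 2 CD39 UMIs, matched cells, a split of cells with 0 CD39 UMIs by the centred log ratio, removal of cells with over 5000 antibody UMIs or with a myeloid UMI, removal of cells high in myeloid antibodies, mean centred log ratios with limma, gate antibodies kept in the adjustment, and counting cells with a UMI of a gene in place of its UMIs. Cells high in myeloid antibodies were those whose share of CD11c, CD14, CD32, CD33 and CD64 UMIs lay over the 99th percentile of CD8-gate cells in their library. A contrast of CD103-positive with CD103-negative cells of the CD8 gate was added as well.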

Results

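The series asks what CD39, an ectonucleotidase on the cell surface encoded by ENTPD1, marks on CD8 T cells of patients with lung cancer. RNA and surface proteins were counted in the same CD3+ cells, pooled from 4 hashtags in 2 libraries that form 1 group. Library 1 held 1285 kept cells with a median of 3911 RNA and 353 antibody UMIs, and library 2 held 784 with medians of 3374 and 1089. After removal of doublets and negatives, hashtags 1 to 4 marked 825, 539, 297 and 190 cells. The CD8 gate held 792 cells and the CD4 gate 845. The labels do not say which specimen or patient a hashtag marks, so values below are per hashtag.

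The hashtags differed in which T cells they held. All 845 cells of the CD4 gate were under hashtags 1 and 2, which marked 1364 cells. Hashtags 3 and 4 gave 0 CD4-gate cells of 487, which allows a share of up to 0.755% (exact upper limit). RNA of CD4 followed the antibody: 16.6% of cells under hashtags 1 and 2 had a CD4 UMI (exact interval 14.7 to 18.7%, median 4098 RNA UMIs), and 0.205% under hashtags 3 and 4 (0.00520 to 1.14%, median 3098). In the CD8 gate, which should lack CD4, the share was 0.505%. CD103, an integrin chain of resident T cells, was found by antibody on 76.9% of CD8-gate cells under hashtag 3, on 38.0% under hashtag 4, on 30.3% under hashtag 2 and on 9.04% under hashtag 1.

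The CD39 antibody was found most often in 5 of the 14 RNA clusters. A regulatory T-like cluster with FOXP3 and IL2RA among its top genes had a CD39 UMI in 58.9% of its 56 cells (exact interval 45.0 to 71.9%). Among CD8 cells, a resident memory-like cluster with XCL1 and CXCR6 had one in 57.1% of 91 cells, and a cluster with KIR2DL4, KLRC1 and KLRC2, genes shared with NK cells, in 63.4% of 41 cells. The latter met the markers of resident memory cells, but its type was left open, and 29 of its 41 cells were in the CD8 gate. A dysfunctional CD8-like cluster with CXCL13 and HLA-DRA had one in 41.2% of 136 cells, and a proliferating cluster with MKI67 in 33.3% of 42 cells. In naive-like cells, used as background, the share was 10.5% of 380 cells (7.63 to 14.1%). These shares pool libraries of unequal antibody depth. In libraries 1 and 2 they were 55% and 68.8% in the regulatory T-like cluster, 42.6% and 86.7% in the XCL1 cluster, 66.7% and 50% in the KIR2DL4 cluster, 34.4% and 55.8% in the dysfunctional-like and 20% and 52.9% in the proliferating cluster.

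At an equal depth of 200 antibody UMIs the shares were 30.9% in the regulatory T-like cluster, 28.3% in the XCL1 cluster, 31.5% in the KIR2DL4 cluster, 15.02% in the dysfunctional-like, 8.86% in the proliferating and 4.60% in naive-like cells. By library the KIR2DL4 cluster still had 34.6% and 18.8% (33 and 8 cells), and the XCL1 cluster 23.8% and 37.2%. The RNA of ENTPD1 had the same background: 1.58% of naive-like cells had a UMI (median 4431 RNA UMIs). The share was 21.3% in the dysfunctional-like cluster (median 6188), 14.3% in the proliferating cluster (9396), 12.5% in the regulatory T-like cluster (3648), 13.2% in the XCL1 cluster (2843) and 9.76% in the KIR2DL4 cluster (3204). At an equal depth of 2000 RNA UMIs the order changed: 9.90% in the XCL1 cluster, 6.99% in the KIR2DL4 cluster, 8.15% in the dysfunctional-like, 6.72% in the regulatory T-like, 3.07% in the proliferating and 0.504% in naive-like cells. Cells under that depth were left out, so 79 of 91 cells of the XCL1 cluster and 134 of 136 of the dysfunctional-like cluster entered. The CD8 clusters high in CD39 mostly came from 1 hashtag each: hashtag 3 gave 98.9% of the XCL1 cluster, hashtag 4 gave 97.6% of the KIR2DL4 cluster and hashtag 2 gave 94.1% of the dysfunctional-like cluster. Hashtag 2 also gave 95.2% of the proliferating cluster. Clusters lower in CD39 varied in this: the largest share from 1 hashtag was 42.2% in the CD8 T-like cluster of 206 cells. It was 82.9% (hashtag 1) in a naive-like cluster of 111 cells, of which 52 were in the CD8 gate. A further resident memory-like cluster, of 145 cells with KLRC1 and ITGAE, had a CD39 UMI in 14.5% (9.19 to 21.3%), near the background. Hashtag 3 gave 73.1% of that cluster.

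**Figure D1:**
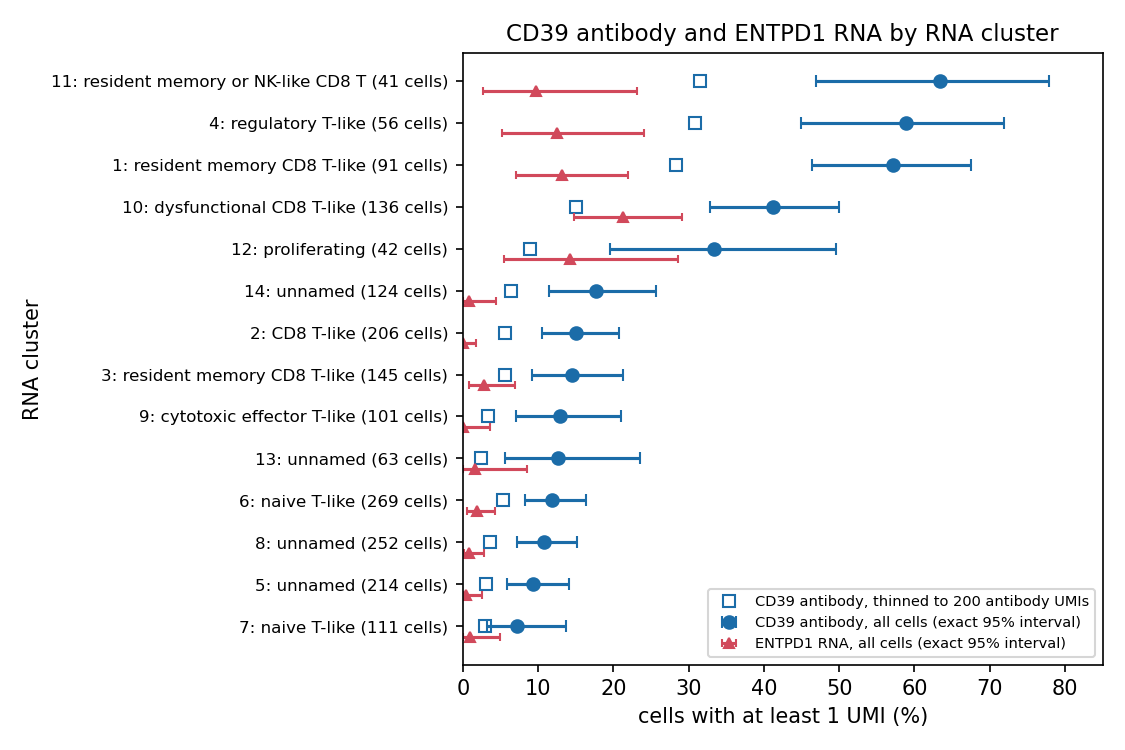
Share of cells with at least 1 UMI (x axis, percent) of the CD39 antibody (circles, with exact 95% intervals), of the CD39 antibody after thinning to 200 antibody UMIs (squares) and of ENTPD1 RNA (triangles, with exact 95% intervals) in each of the 14 RNA clusters (y axis). The regulatory T-like cluster, cluster 1 (with XCL1), cluster 11 (with KIR2DL4), the dysfunctional-like and the proliferating cluster lie between 33.3% and 63.4% for the antibody, and the naive-like clusters at 7.21% and 11.9%.

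The share of cells with CD39 was compared between CD8 and CD4 T cells. At least 1 CD39 UMI was found in 21.8% of CD8-gate cells (exact interval 19.0 to 24.9%, median 440 antibody UMIs) and in 14.2% of CD4-gate cells (11.9 to 16.7%, median 422). At 200 antibody UMIs these shares were 9.75% and 5.70%. The naive-like background was 10.5% (7.63 to 14.1%), and 4.60% at 200 antibody UMIs, so the CD4 share lay near it. A CD39 count over the isotype limit (99th percentile) was found in 1 of 792 CD8-gate and 1 of 845 CD4-gate cells. A single CD39 UMI therefore does not by itself show CD39 on a cell. By hashtag, the CD8 shares were 14.7%, 21.3%, 27.7% and 20.9% under hashtags 1 to 4, and the CD4 shares were 12.5% and 18.4% under hashtags 1 and 2. Within the hashtags that held both gates, the CD8 share was higher by a mean of 2.52 percentage points (exact sign-flip permutation p = 0.5, n = 2 hashtags, the smallest p that 2 hashtags allow). The classes by tertile fix the share by construction, and the mean difference there was -0.37 points (exact permutation p = 1). The libraries differed with depth: 15.6% of CD8-gate cells in library 1 and 34.1% in library 2 had a CD39 UMI, against 9.13% and 10.9% at 200 antibody UMIs.

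RNA of ENTPD1 was compared with the antibody as a check of the classes. In the CD8 gate, 7.96% of cells in the top CD39 tertile had an ENTPD1 UMI (exact interval 4.99 to 11.9%) and 2.65% in the bottom tertile (1.07 to 5.39%). By CD39 UMI the shares were 12.1% (7.67 to 18.0%) and 2.75% (1.61 to 4.36%). The share was higher with CD39 in 4 of 4 hashtags under either definition, on small counts. Under hashtag 1 it was 1 of 26 cells against 1 of 151 by CD39 UMI, and 2 of 60 against 0 of 44 by tertile. In the CD4 gate the shares by CD39 UMI were 6.67% (2.92 to 12.7%) and 0.966% (0.389 to 1.98%), higher in 2 of 2 hashtags, and 3.90% and 1.06% by tertile. The classes were mixed: 152 of 264 CD8-gate cells in the top tertile had a CD39 UMI, and 1 of 264 in the bottom tertile. In the CD4 gate, 105 of 282 and 13 of 282 had one.

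CD8 T cells with CD39 carried more RNA of CXCL13, which encodes a chemokine that attracts B cells and is a known product of dysfunctional tumour-infiltrating CD8 T cells. CXCL13 (ENSG00000156234) was at 510.3 ± 663 CPM in the top tertile and at 178 ± 251 in the bottom tertile (SD, n = 4 hashtags), a log2 fold change of 1.57 (SE 0.19, adjusted p = 0.00029), higher in 4 of 4 hashtags. By CD39 UMI the log2 fold change was 1.76 (SE 0.26, adjusted p = 0.0021), again in 4 of 4 hashtags. A CXCL13 UMI was found in 32.4% of 173 cells with a CD39 UMI (median 3276 RNA UMIs) and in 9.53% of 619 without (median 3342), against 0 of 380 naive-like cells (exact upper limit 0.966%). CXCR6, a chemokine receptor of resident T cells, rose by CD39 UMI (log2 fold change 1.66, SE 0.23, adjusted p = 0.0015), from 76.4 ± 16.4 to 254 ± 168 CPM.

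Genes of naive and recirculating T cells were lower in CD8 cells with a CD39 UMI. IL7R, the receptor chain for the survival cytokine IL-7, fell by 0.97 on the log2 scale (SE 0.15, adjusted p = 0.0042), and CCR7, which guides cells to lymph nodes, fell by 1.31 (SE 0.27, adjusted p = 0.041). The stress-induced GADD45B fell by 1.42, the long noncoding RNA LINC00861 by 1.18, and the translation genes RPS16, RPS12, RPL3 and EEF1A1 by 0.55, 0.53, 0.53 and 0.47. All of these had the same sign in 4 of 4 hashtags, and their adjusted p lay between 0.0042 and 0.0492.

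By tertile, edgeR called 1 gene up and 1 down of 3293 (152 at an unadjusted p under 0.05), and the gene that fell is a receptor segment. By CD39 UMI, 2 rose and 10 fell of 4577 (394 unadjusted), 2 of them receptor segments. The counts moved with single hashtags: by tertile they were 21, 6 and 4 without hashtags 1, 2 and 4, and by CD39 UMI 71 without hashtag 2 and 2 without hashtag 3. Of the 12 genes by CD39 UMI, 7, 12, 1 and 9 were again called without hashtags 1 to 4, and CCR7 had adjusted p = 0.0627 without hashtag 1. Without hashtag 3, by CD39 UMI, CXCL13 kept a log2 fold change of 1.73 with adjusted p = 0.0635, CXCR6 1.31 with 0.0796, IL7R -0.81 with 0.152 and CCR7 -1.02 with 0.212, and by tertile CXCL13 had adjusted p = 0.0342. When cells with a UMI were counted in place of UMIs, CXCR6 alone passed by CD39 UMI (1.18, adjusted p = 0.0048), no gene passed by tertile (65 unadjusted with edgeR, 1 gene with DESeq2 on UMIs), and CXCL13 fell under the gene filter of those fits.

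**Figure D2:**
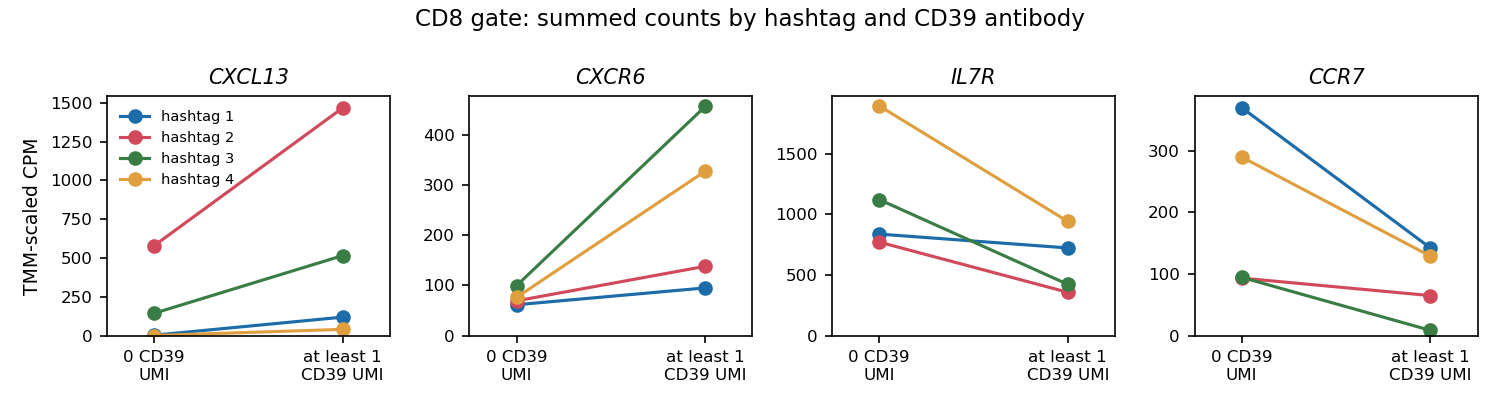
Summed counts scaled by TMM (y axis, CPM) of CXCL13, CXCR6, IL7R and CCR7 in CD8-gate cells with 0 and with at least 1 CD39 UMI (x axis), with 1 line per hashtag. CXCL13 and CXCR6 were higher, and IL7R and CCR7 lower, with CD39 in 4 of 4 hashtags.

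Among the gene lists, CD8 dysfunction and tumour reactivity was higher by CD39 UMI: 11 of 12 tested members were positive, CXCL13 rose, and 7 passed when adjusted over the list alone. Examples are ACP5 at 1.01, VCAM1 at 0.83, PHLDA1 at 0.82 and the transcription factor TOX at 0.75 on the log2 scale, with adjusted p of 0.0602, 0.255, 0.227 and 0.3 over all genes. The naive and central memory list was lower, with 13 of 13 members negative. IL7R and CCR7 fell, and 9 members passed when adjusted over the list alone, LEF1 at -1.47 among them. These lists passed camera (adjusted p = 1.8e-11 and 6.3e-15) and kept adjusted p = 0.0344 each with an estimated correlation. In cells matched on antibody total they had camera adjusted p = 6.6e-04 and 9.7e-06, and did not pass with an estimated correlation (adjusted p = 0.138 each).

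MHC class II with CD74, the antigen presentation genes that activated human T cells also express, was positive for 9 of 9 members by CD39 UMI (median 0.56). No member rose over all genes, 6 passed when adjusted over the list alone, and the camera adjusted p of 3.7e-11 became adjusted p = 0.0746 with an estimated correlation (1.2e-09 and 0.179 in matched cells). Tissue residency was positive for 11 of 13 members, where CXCR6 rose and 3 passed over the list alone (2.8e-05, and adjusted p = 0.134 with an estimated correlation). Circulating effector genes were negative for 7 of 7, with KLRG1 at -1.26 (1.0e-04, and adjusted p = 0.243 with an estimated correlation). Dissociation stress genes were negative for 8 of 10 (0.0073, and adjusted p = 0.143 with an estimated correlation).

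Cytotoxicity (camera adjusted p = 0.101), regulatory T cell (0.0979), interferon response (0.318), proliferation (0.318) and NK genes (0.518) did not pass by CD39 UMI. The T follicular helper, MAIT, receptor-induced early, myeloid, and stromal and endothelial lists had 1 or 2 tested members, and the B and plasma, epithelial, and erythrocyte and platelet lists had 0. By tertile, 4 lists passed camera: MHC class II (8 of 8 positive, median 0.45, adjusted p = 2.1e-07), proliferation (4 of 5 negative, adjusted p = 2.8e-05), CD8 dysfunction (10 of 12 positive, adjusted p = 0.0166) and naive and central memory (median -0.04, adjusted p = 0.0233). None of the 4 passed with an estimated correlation (adjusted p = 0.374, 0.189, 0.374 and 0.374).

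Surface proteins were compared in the same CD8 cells, and no protein passed with edgeR. Of the kept cells, 24 in library 1 and 30 in library 2 had over 5000 antibody UMIs. They held 43.5% and 40.3% of the antibody UMIs of their library, so summed proteins can follow a few cells. Without these cells the tertile count in the CD8 gate was again 0. By tertile 0 of 134 were called (8 unadjusted, and 1 with DESeq2), by CD39 UMI 0 (23 unadjusted), and in cells matched on antibody total 0 (18 unadjusted, and 0 with limma). The integrin CD49f had the smallest p in matched cells: it was at -1.30 on the log2 scale (SE 0.22, adjusted p = 0.0608), lower in 4 of 4 hashtags. KLRG1, a receptor of circulating effector cells, was at -0.92 and the dipeptidyl peptidase CD26 at -0.78 (adjusted p = 0.185 and 0.192). CD49f and CD26 were singled out after their values were seen. CD103 at 0.88 passed when adjusted over the residency list alone, as did KLRG1 over the circulating effector list. Over the naive and memory list alone 1 protein passed higher and 2 lower. With limma on mean centred log ratios by tertile the adhesion receptor CD44 fell (difference -0.37 on the natural log scale, SE 0.051, adjusted p = 0.0387, lower in 4 of 4 hashtags), a difference in which the antibody total of the cells also enters.

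No protein list passed camera in the CD8 gate by tertile (adjusted p from 0.852 to 0.91) or in matched cells (0.185 to 0.839), and fry gave adjusted p = 0.0043 for activation and dysfunction in matched cells, with 11 of 14 positive. By CD39 UMI without matching, naive and memory proteins passed camera (adjusted p = 0.0391, and adjusted p = 0.346 with an estimated correlation). In that comparison the activation and dysfunction, residency, circulating effector, and other lineage proteins had camera adjusted p of 0.394, 0.394, 0.555 and 0.999. By tertile the residency list had a median of -0.18 and a mean of -0.22 while camera pointed up, and the circulating effector list had a median of -0.07 and a mean of 0.19.

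CD4 T cells with a CD39 UMI carried more RNA of regulatory T cell genes. FOXP3 (ENSG00000049768), the transcription factor that defines regulatory T cells, was at 66.8 ± 31.3 CPM with CD39 and at 8.4 ± 3.7 without (SD, n = 2 hashtags), a log2 fold change of 2.96 (SE 0.42, adjusted p = 1.5e-09). IKZF2, another transcription factor of these cells, rose by 2.79 (SE 0.42), the inhibitory receptor TIGIT by 2.35 (SE 0.28), RTKN2 by 2.29 (SE 0.39) and TOX by 2.11 (SE 0.47). A FOXP3 UMI was found in 17.5% of 120 cells with a CD39 UMI (median 4032 RNA UMIs) and in 2.48% of 725 without (median 4263), against 0.789% of naive-like cells (0.163 to 2.29%, median 4431) and 0.126% of CD8-gate cells (median 3330). Each was higher in 2 of 2 hashtags.

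Antigen presentation genes rose with them: 9 of 9 tested members of MHC class II with CD74 passed the test over all genes. HLA-DRB1 rose by 2.18 on the log2 scale (SE 0.25, adjusted p = 9.3e-15), HLA-DQB1 by 2.19, HLA-DMA by 2.27 and CD74 by 1.72 (SE 0.17, adjusted p = 3.3e-21). HLA-DRB1 and HLA-DRB5 are near-identical paralogs, so reads can be shared between them. An HLA-DRB1 UMI was found in 27.5% of cells with a CD39 UMI and in 8.83% without, against 8.16% of naive-like cells (median 4431 RNA UMIs). The lipid carrier FABP5 (2.40) and the glycerol kinase GK (2.12) rose as well, and 64.6% of the FABP5 counts with CD39 came from 1 cell. The largest share from 1 cell was 28.0% for HLA-DRB1, 25.9% for HLA-DQB1, 34.5% for HLA-DMA and 23.3% for CD74. With CD39, HLA-DRB1 was at 367 ± 373 CPM (SD, n = 2 hashtags), so its level was uneven between the hashtags. HLA-DRB1, HLA-DQB1, GZMA and GZMK were also top genes of the dysfunctional-like cluster, which had 9 of its 136 cells in the CD4 gate. What those cells add to the difference was not tested.

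The genes lower in CD4 cells with a CD39 UMI included cell division and stress genes. Division genes were uneven between the hashtags: without CD39, NUSAP1 was at 37.1 ± 49 CPM and STMN1 at 273 ± 226 (SD, n = 2 hashtags). The proliferating cluster came to 95.2% from hashtag 2. GNLY, a cytotoxic granule protein, was listed at 0 of 120 cells with CD39. Its 125 counts in the others came from 12 of 725 cells (1.66%), and 1 cell gave 28.8% of them. With 3 counts over the class in place of 0 the summed counts were 7.54-fold lower, a value that rests on these few cells. STMN1 fell by 1.49, TUBA1B by 1.41, NUSAP1 by 2.19, MYBL1 by 2.20, GPR65 by 1.39, GPR183 by 1.17 and GADD45B by 1.40 on the log2 scale. The heat shock gene HSPA1B fell by 3.14 and HSPH1 fell by 1.26. For HSPA1B, 82.4% of the counts without CD39 came from 1 cell, and a UMI was found in 7.5% of cells with CD39 and in 4.41% without. A NUSAP1 UMI was found in 3.33% of cells with CD39 and in 2.62% without, and a STMN1 UMI in 26.7% and 29.7%, so the fall of NUSAP1 rested on counts per cell.

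By CD39 UMI, edgeR called 78 genes up and 40 down of 6381 in the CD4 gate (590 unadjusted), 17 of them receptor segments. Of these 118 genes, 107 had the same sign in both hashtags. The fit rests on 2 hashtags, so its small p-values lean on the spread shared over genes, and DESeq2 called 2 genes. In matched cells 39 were called, where FOXP3 had a log2 fold change of 1.79 (SE 0.59, adjusted p = 0.207). When cells with a UMI were counted in place of UMIs, 10 genes passed, all of them higher and all among the 118: FOXP3, IKZF2, TIGIT, CTLA4, TOX, HLA-DRB1, HLA-DQB1, HLA-DPA1, C15orf53 and ZC2HC1A. CD74 had 0.30 there (adjusted p = 0.998).

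**Figure D3:**
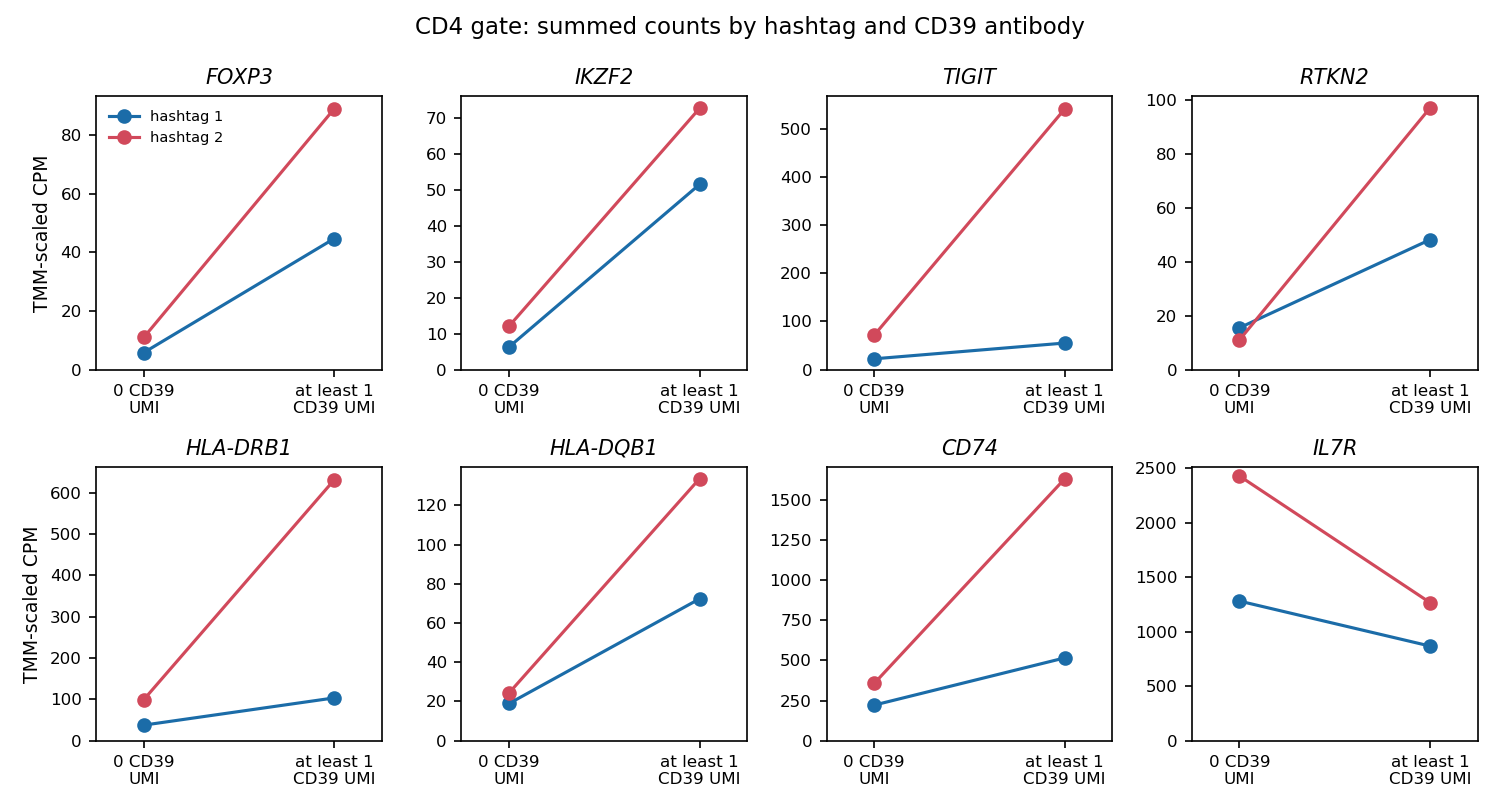
Summed counts scaled by TMM (y axis, CPM) of 8 genes in CD4-gate cells with 0 and with at least 1 CD39 UMI (x axis), with 1 line for each of the 2 hashtags that held CD4-gate cells. FOXP3, IKZF2, TIGIT, RTKN2, HLA-DRB1, HLA-DQB1 and CD74 were higher with CD39, and IL7R (log2 fold change -0.75) was lower, in 2 of 2 hashtags.

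By list, 6 lists passed camera in the CD4 gate by CD39 UMI, and none of the 6 passed with an estimated correlation: adjusted p = 0.337 for each except cytotoxicity, which had adjusted p = 0.43. Of the regulatory T cell genes 7 of 13 rose, 0 fell and 13 were positive (camera adjusted p = 4.2e-29, and adjusted p = 0.337 with an estimated correlation). MHC class II with CD74 had camera adjusted p = 5.7e-51 (0.337 with an estimated correlation). Of the CD8 dysfunction list, 5 of 14 rose, among them CTLA4, CD27 and ACP5 (1.9e-12), and 5 of 9 proliferation genes (5.4e-06) and 3 of 12 dissociation stress genes (1.5e-08) fell. Of the cytotoxicity list, GZMA, GZMK and CST7 rose and GNLY fell (0.0064). Its median was 0.43 and its mean -0.39, or 0.17 with GNLY at its bound. By tertile this list pointed down (median -0.61, camera adjusted p = 1.6e-04, and 0.378 with an estimated correlation, 3 lower when adjusted over the list alone), and in matched cells up (adjusted p = 1.5e-05, and adjusted p = 0.508 with an estimated correlation). Dissociation stress pointed up by tertile (11 of 13 positive, adjusted p = 3.2e-06, and 0.378 with an estimated correlation), and in matched cells 0 of 9 fell (adjusted p = 0.998), so neither list kept its direction.

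The remaining lists did not pass in the CD4 gate by CD39 UMI: naive and central memory (camera adjusted p = 0.126), MAIT (0.145), interferon response (0.207), receptor-induced early genes (0.273), T follicular helper (0.299), tissue residency (0.527) and circulating effector (0.991). Of the myeloid, NK, epithelial, and erythrocyte and platelet lists 0 members were tested, and 1 each of the B and plasma list (0.75) and the stromal and endothelial list (0.86).

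By tertile, the CD4 gate gave 7 genes up and 2 down of 6971 (370 unadjusted with edgeR, and 0 genes with DESeq2). TIGIT rose by 1.59 on the log2 scale (SE 0.28), the inhibitor of NF-kappa-B NFKBIA by 1.10, the early response gene NR4A2 by 2.67, GADD45B by 1.84 and the heat shock gene HSPB1 by 1.72. In the top tertile, 1 cell gave 85.5% of the NR4A2, 37.7% of the GADD45B and 31.6% of the HSPB1 counts. By CD39 UMI, GADD45B and HSPB1 fell by 1.40 and 1.13, and NFKBIA was at -0.31, so their direction by tertile did not follow the CD39 UMI. The lists by tertile were led by regulatory T cell genes (14 of 14 positive, median 1.15, camera adjusted p = 3.3e-17), and 9 lists passed, none of them with an estimated correlation (adjusted p = 0.378 or higher).

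No surface protein passed with edgeR in the CD4 gate: by tertile 0 of 134 were called (11 unadjusted, 4 with DESeq2 and 0 with limma), by CD39 UMI 0 (24 unadjusted), and in matched cells 0 (11 unadjusted, and 0 with limma). Without cells over 5000 antibody UMIs, 2 were called by tertile. Since few cells can carry the summed proteins, a count of 0 does not show that proteins were equal. The ectoenzyme CD38 had the smallest p by tertile, at -3.03 on the log2 scale (adjusted p = 0.0521), and by CD39 UMI it was at 4.23 (adjusted p = 0.248), the opposite direction, while in matched cells it was at 0.49 (adjusted p = 0.553). In matched cells HLA-DR was at 1.20 and CD25, the interleukin-2 receptor chain of regulatory T cells, at 1.32 on the log2 scale (adjusted p = 0.482 and 0.553), each higher in 2 of 2 hashtags. CD25 was at 0.66 without matching, with opposite signs in the 2 hashtags. Of the proteins of myeloid and antigen-presenting cells none passed in matched cells. CD32 was at 2.73, CD33 at 2.76, CD11c at 3.38 and CD40 at 1.21 (adjusted p = 0.373, 0.482, 0.482 and 0.482), each positive in 2 of 2 hashtags. So was CD64 at 1.485 (adjusted p = 0.6085), while CD86 at -0.454 was negative in 2 of 2. CD14 at 0.71, CD328 at 1.29, CD11b at 0.49, CD163 at -0.14 and CD36 at -0.17 had opposite signs in the 2 hashtags (adjusted p from 0.732 to 0.911). These were positive in hashtag 2 and negative in hashtag 1, so all named here except CD86 were higher with CD39 in hashtag 2. Before matching, the largest share of UMIs from 1 cell with CD39 was 67.8% for CD11c, 54.3% for CD14 and 51.6% for CD33. For CD32 and CD64 it was 46.0% and 26.8%, so these differences can rest on few cells. The proteins in these comparisons of matched cells were singled out after their values were seen. Of the protein lists by tertile none passed camera (adjusted p from 0.178 to 0.904), and fry gave adjusted p = 0.0036 for naive and memory proteins, with 6 of 7 positive.

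The CD39 contrast itself was compared between CD8 and CD4 T cells of hashtags 1 and 2. By CD39 UMI, class II and TIGIT genes differed: CD74 by -1.51 on the log2 scale (SE 0.25, adjusted p = 0.0040), HLA-DRB1 by -1.83, HLA-DPA1 by -1.62 and TIGIT by -1.95, each with a smaller difference in the CD8 gate. CD74 was at 2586 CPM with CD39 and at 1643 without in the CD8 gate, and at 1001 and 241 in the CD4 gate. In all, edgeR called 5 genes with a higher and 8 with a lower contrast in the CD8 gate of 6471 (316 unadjusted), 2 of them receptor segments, and DESeq2 called 0 (44 unadjusted). By tertile, edgeR called 1 gene of 5433 (210 unadjusted), a receptor segment, and DESeq2 called 0.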

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

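Tests chosen only after the result was seen were those by CD39 UMI, those in matched cells, and the RNA test of the missing CD4 cells. The depth split of cells without a CD39 UMI and the removals of cells with a myeloid UMI or high in myeloid antibodies were added after the data had been seen, but their bounds were written before their own results were seen. The fits without each hashtag were planned, with their bound written before as well.

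Higher CXCL13 in CD8-gate cells with CD39 was weighed against antibody depth and against a single hashtag. In cells matched on antibody total the log2 fold change was 1.84 (SE 0.31, adjusted p = 0.0074), against 1.76 unmatched, which argues against depth as the whole cause. When cells with 0 CD39 UMIs were split by centred log ratio, CXCL13 differed by 0.33 with an upper 95% limit of 1.03, above the bound of 0.88, so a share from depth could remain. This limit used the residual degrees of freedom of the hashtags alone, without the moderation behind the p-values, which makes it wider. By tertile the highest adjusted p without any 1 hashtag was 0.0342, while by CD39 UMI it was 0.0635 without hashtag 3, with a log2 fold change of 1.73. A candidate explanation is that CD39 marks the dysfunctional cells that make CXCL13, which stays a hypothesis, since no group in the labels tests it. The dysfunctional-like cluster held 128 cells of hashtag 2 and 6, 1 and 1 of hashtags 1, 3 and 4. That cluster alone could therefore hardly make the difference under hashtags 3 and 4.

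Other splits of the 8 sums were counted for the CD8 gate. By CD39 UMI, 3 of 32 splits gave at least the real 12 genes and the highest of the others gave 20, so chance was not excluded. Of the 8 splits that part all 4 pairs as the real one does, the highest other gave 1, but 8 splits cannot give a share under 0.05. By tertile, 12 of 32 splits gave at least the real 2 genes (highest other 7), and for proteins 32 of 32 gave at least the real 0 (highest other 1 by tertile with edgeR and 0 in matched cells with limma). For CD103 and genes, 32 of 32 gave at least the real 0, the highest other gave 56, and among the 8 that part all pairs the highest other gave 2. A real count of 0 fixes these shares, and why a split gave 56 was not tested.

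Higher regulatory T cell and class II genes in CD4-gate cells with a CD39 UMI were weighed against doublets with myeloid cells and against depth. Without cells with a myeloid UMI, CD74 kept 1.81 and FOXP3 3.02 on the log2 scale. Without cells high in myeloid antibodies (2 of 120 cells with CD39 and 8 of 725 without) they kept 1.72 and 3.003. The names of these myeloid antibodies had no check against RNA. The removals took 4 and 2 of the 120 cells with CD39. They show that the removed cells did not make the difference. So few cells were removed that myeloid doublets missed by these limits cannot be excluded. Antibodies against myeloid proteins still went the same way as CD39: CD11c was found on 24.2% of cells with a CD39 UMI and on 9.93% without, CD33 on 15% and 4.69%, and CD64 on 28.3% and 12.4%. These shares are not at equal depth, and a CD39 UMI selects deeply counted cells. In the CD8 gate CD11c was found on 30.1% and 14.7%, CD33 on 10.4% and 4.85%, and CD64 on 17.9% and 13.9%. In CD4-gate cells with CD39, the largest share from 1 cell was 67.8% for CD11c, 51.6% for CD33, 46.0% for CD32 and 26.8% for CD64. The list of other lineages was positive for 10 of 11 proteins (camera adjusted p = 0.0821), and 8 of 11 in matched cells (adjusted p = 0.482). Why these antibodies were higher was left open. In matched cells CD74 kept 1.86, HLA-DRB1 2.43 and TIGIT 2.57, which argues against depth for these 3 genes, and FOXP3 went from 2.96 (SE 0.42) to 1.79 (SE 0.59, adjusted p = 0.207) with fewer cells. Counted as cells with a UMI, CD74 was at 0.30 and did not pass. A CD74 UMI was found in 57.5% of cells with CD39 and in 43.3% without, so more cells carried it, and its fold change also drew on more UMIs per cell. Of the 56 cells in the regulatory T-like cluster, 52 were in the CD4 gate and 22 and 34 were under hashtags 1 and 2. A CD39 UMI was found in 58.9% of them, against 14.2% of the gate. No biological explanation was tested, since the labels give no group for it.

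The absence of CD4-gate cells under hashtags 3 and 4 was weighed against a failure of the CD4 antibody. If the antibody had failed there, CD4 RNA would still have been found, yet 0.205% of those cells had a CD4 UMI against 16.6% under hashtags 1 and 2. This argues against the antibody as the cause. Sorting, specimen type and patient stay open, and no biological explanation was tested, since the labels do not say what each hashtag marks.

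The CD39 contrast by UMI differed between the gates, by a test of the difference itself, for 10 named genes. In CD8 minus CD4 log2 values, MKI67, TOP2A and UBE2C were listed at 0 counts in CD4-gate cells with CD39, and with 3 counts over the class in their place the differences in pooled counts were 3.92, 3.54 and 3.50. CENPF at 4.57, also a ratio of pooled counts (4.64 as fitted), had 3 counts there (ratio with to without CD39 0.103, counting interval 0.0211 to 0.308), and ASPM at 4.24 (4.40 as fitted) had 2 (0.103, 0.0123 to 0.38). The counts of these 5 genes in CD4-gate cells without CD39 came from 12, 14, 12, 19 and 13 of 725 cells. In CD8-gate cells with CD39, 1 cell gave 40.3%, 44.2%, 41.9%, 52.0% and 58.8% of them, so these differences rest on few cells. Of the 42 cells in the proliferating cluster, 40 were under hashtag 2. As fitted values, HMOX1 was at -4.74, where 1 cell gave 93.5% of the counts of CD4-gate cells with CD39. TIGIT was at -1.95, HLA-DRB1 at -1.83, HLA-DPA1 at -1.62 and CD74 at -1.51, and DESeq2 called 0 genes in this comparison (44 at an unadjusted p under 0.05, against 316 with edgeR).

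Mouse genes, which the comparisons did not use, took 1.02% of the UMIs in library 1 and 2.28% in library 2, with 10 and 37 barcodes over 10% mouse UMIs. Of 16 sets of 4 hashtag values, 0 held a value far from the others by Dixon's test.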

How the results depend on the processing

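Tests chosen only after the results or the data were seen were those with CD39 UMI classes, matched cells, the depth split, cells with a UMI, removal of cells over 5000 antibody UMIs or with a myeloid UMI, removal of cells high in myeloid antibodies, gate antibodies kept in the adjustment, limma, and the CD103 contrast. Unless a construction is named, the cause of a change was not tested.

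CXCL13 in CD8 tertiles kept its direction under 17 alternatives and its side of the threshold under 14, with log2 values from 0.33 to 1.84. The count in CD8 tertiles was 2 genes. It was 1 with DESeq2, 0 without the hashtag block, 0 with the hashtag within a library as unit, 0 with cells with a UMI, 18 without the gene filter, 24 by ENTPD1 UMI (hashtags 2 and 3 alone), 8 with the library as unit, 12 by at least 1 and 18 by at least 2 CD39 UMIs (the latter without hashtag 1, which had under 10 such cells), and 10 in the depth split. Without each hashtag it ranged from 3 to 21. Where edgeR gave 0, 46 to 71 genes had an unadjusted p under 0.05.

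In CD8 cells by CD39 UMI, 12 genes were called, and 54 with DESeq2 (6 shared), 0 without the block (134 unadjusted), 106 without the filter, 3 in matched cells (fewer cells), 43 without cells over 5000 antibody UMIs, 49 without cells with a myeloid UMI, 234 with the library as unit, which adds up hashtags, and 1 with cells with a UMI. Without each hashtag the count ranged from 2 (hashtag 3) to 71 (hashtag 2). The named genes kept their direction and their side of the threshold in 85 fits, kept the direction alone in 53 and reversed in 0.

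In CD4 tertiles 9 genes were called, and 0 with DESeq2, 0 without the block, 0 with cells with a UMI, 0 with the hashtag within a library (30 to 360 unadjusted in these 4 fits), 87 without the gene filter, 17 without the cell filter, 29 without the top 2% of cells by UMIs, 5 with the library as unit, 118 by at least 1 and 120 by at least 2 CD39 UMIs, 39 in matched cells, 3 in the depth split and 20 without cells over 5000 antibody UMIs. Signs reversed for genes named there. GADD45B went to -0.091 with cells with a UMI, -0.052 with the gate by RNA, -1.40 by at least 1 and -1.73 by at least 2 CD39 UMIs, and -0.43 in matched cells. HSPB1 went to -0.04 with cells with a UMI, -1.13 and -1.02 by at least 1 and 2 CD39 UMIs, and -0.38 in matched cells. NFKBIA went to -0.11 with the gate by RNA, -0.31 and -0.85 by at least 1 and 2 CD39 UMIs, and -0.55 in matched cells. NR4A2 went to -1.96 by at least 2 CD39 UMIs and TIGIT to -1.01 in the depth split.

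In CD4 cells by CD39 UMI 118 genes were called, and 2 with DESeq2 (2 shared), 0 without the block (253 unadjusted), 39 in matched cells (33 shared, fewer cells), 206 with the library as unit, 61 without cells high in myeloid antibodies (61 shared) and 10 with cells with a UMI (10 shared). The named genes kept direction and side in 117 fits, direction alone in 68 and reversed in 0.

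For proteins of CD8 tertiles edgeR called 0, as it did without each hashtag (0 to 0), and 1 without TMM, against 1 with DESeq2 and 1 with limma on centred log ratios. In 15 alternatives the count was 0 (5 to 25 unadjusted). For CD4 tertiles edgeR called 0, and 1 with gate antibodies kept in the adjustment, 4 with isotype controls as library size and 2 without cells over 5000 antibody UMIs, against 4 with DESeq2. In 9 alternatives the count was 0 (4 to 31 unadjusted).

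The contrast between gates gave 1 gene, 0 with DESeq2, 23 without the gene filter, 13 by CD39 UMI and 0 by CD39 UMI with DESeq2 (13 to 44 unadjusted in the DESeq2 fits). For CD103, edgeR called 0 genes (357 unadjusted), DESeq2 20, and without each hashtag 0 to 21. Of the lists, 4 passed in CD8 tertiles, 0 with an estimated correlation and 7 with the library as unit. In CD4 tertiles 9 passed, 0 with an estimated correlation and 5 in matched cells. The share difference of -0.37 points was 2.52 by CD39 UMI, and -2.87 to 2.13 without each hashtag (2.13 without hashtag 1). The difference in ENTPD1 share was 9.39 points in CD8 and 5.70 in CD4 cells by CD39 UMI, against 5.30 and 2.84 by tertile. Clusters numbered 14, and 9 at resolution 0.5.

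Not run were fits without a hashtag in the CD4 gate and between gates (1 hashtag left, no residual degrees of freedom), classes by the isotype limit (at most 1 cell passed per gate) and ENTPD1 classes in the CD4 gate (no hashtag with 10 cells). Antibody depth changes the classes: at 200 antibody UMIs a CD39 UMI was found in 9.75% of CD8-gate cells against 21.8% at full depth.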

Other observations

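The CD103 contrast below and its tests were chosen only after the data were seen. CD8-gate cells with CD103 antibody, a mark of resident T cells, were compared with CD8-gate cells without it over 4 hashtags. With edgeR 0 of 4457 genes passed (357 at an unadjusted p under 0.05), and DESeq2 called 20. CXCR6 was at 1.96, CXCL13 at 2.49 and FGFBP2 at -3.93 on the log2 scale (adjusted p = 0.0716 for each), with the same sign in 4 of 4 hashtags, and these 3 genes were singled out after their values were seen. Without hashtags 1 to 4 the count was 5, 21, 6 and 0.

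Camera put the naive and central memory list (13 of 13 negative, adjusted p = 5.6e-13) and the circulating effector list (7 of 7 negative, 2.0e-11) lower with CD103. It put MHC class II with CD74 (9 of 9 positive, 7.4e-08), tissue residency (7 of 10 positive, 1.5e-06) and CD8 dysfunction (7 of 10 positive, 2.2e-06) higher. None of these 5 lists passed with an estimated correlation (adjusted p = 0.153, 0.153, 0.153, 0.26 and 0.153). Of 133 proteins edgeR called 0 (12 unadjusted) and limma 0 (28 unadjusted).

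Cluster 14 held 124 cells, 122 of them in library 2, with a median of 2118 RNA UMIs. Cluster 13, of 63 cells, had NFKBIA, GADD45B and NR4A2 as its top genes.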
